A study of Drosophila melanogaster with 20 samples.

How the data were processed

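Total RNA from dissected fly brains was hybridised to Affymetrix Drosophila 2 arrays, 1 biotin-labelled sample per array, with 20 arrays in 4 groups of 5, per the labels. The groups are wild type and miR-34 null at 3 d and at 20 d. The repeat numbers 1 to 5 in the titles were used as replicate numbers. The deposited table holds 1 intensity per probe set and array. Per the submitters' processing notes the tools were MAS5 and GCRMA, and the labels' descriptions name MAS5 output. The deposited intensity values were linear, ranged from 0.0116 to 3455 and had the same trimmed mean of 150 on every array (2% trimmed at each end), as a MAS5 scaling leaves them. They were used as deposited, with no further normalization. How the arrays were scanned and which parameters were used is not given in the sources used here.

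Of 18952 probe sets, 183 were controls and were left out of the tests. Of the other 18769, 13647 had 1 gene symbol in the platform annotation, 402 had several and 4720 had none, and genes were named only from the first kind. Symbols were checked through gene identifiers against a RefSeq table of the assembly Release 6 plus ISO1 MT, which held all but 103 of the 13647. That table served for names and gene order only, since the array's build is not given in the sources used here. It holds no untranslated regions, so no search for miR-34 sites was run.

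Signals were analysed as log2(signal + 16). A probe set was kept if it lay above its array's median in at least 5 of the 20 arrays, which left 9806 probe sets and 7704 genes. All 20 arrays entered 1 linear model with 4 group means (limma 3.58.1 in R 4.3.3, eBayes with trend and robust settings), so that the groups share an estimate of the spread. The 5 contrasts were null against wild type at each age, 20 d against 3 d in each genotype, and the interaction (change with age in null minus that in wild type). P-values were adjusted by Benjamini-Hochberg per contrast, and probe sets at adjusted p under 0.05 are called higher or lower. On arrays simulated from the real means and spreads with 200 changed probe sets among 9806, the model recovered 72% of changes of 0.25 log2 and 100% of changes of 0.5 or more for null against wild type at 3 d, and 42% and 90% of changes of 0.25 and 0.5 for the interaction. False calls made up 4.21% to 5.13% of the calls over the 5 contrasts. The simulated noise was independent between probe sets and few were changed, so these rates need not hold for the real arrays. A simulated shift of 30% along the ageing score was read as 28.9%, on arrays with no other difference between the genotypes.

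Genes were named by a rule fixed before the data were examined. It took the 10 highest and 10 lowest log2 fold changes of each contrast between 2 groups among called genes whose groups did not overlap, with the probe set of highest mean per gene, and the 5 highest and 5 lowest interactions. It added mir-34, Eip74EF, w, the 5 nearest genes with a probe set on each side of mir-34, and in each gene list the 3 called members with the largest change, or the largest if none was called. From the lists only some of the named members are printed. The 26 gene lists were also fixed then, with 812 names in all, of which 50 were matched through synonyms and 8 were not matched. Many matched names had no probe set of their own or lay below the filter, so some families were measured only in part. Of the listed names, 6 of 15 antimicrobial peptides, 12 of 27 immune-induced genes and 29 of 81 ribosomal proteins were measured. GNMT of the fat body list was not matched to the array's Gnmt, so the fat body counts and tests leave Gnmt out. The lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 130 tests, and again with an estimated correlation. Members are counted over all probe sets tested and also adjusted over the list alone. Besides the pathways and stress responses, the lists mark neurons, glia, photoreceptors, eye pigment, odour- and taste-related genes of the head, fat body, muscle, haemocytes and sex composition. Lists of digestive enzymes, of chitinases, chitin deacetylases and mucins, and of cuticle proteins were added after the values were seen, by symbol patterns, and adjusted among themselves. Their tests describe values already seen, and no list p is given for the digestive enzymes, many of which passed the filter only through the 3 d null arrays.

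The ageing score of an array is its mean log2 signal over the 100 probe sets with the highest moderated statistic for wild-type ageing minus that over the 100 with the lowest. For 3 d brains it was set on 20 d wild type and 2 of the 5 arrays of 3 d wild type, and the other 3 were compared with null, for all 10 choices. For 20 d brains the ages were exchanged.

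As a check of RNA quality, the log2 ratio of 3' to 5' control probe sets of GAPDH, eIF-4a and actin was compared in the 4 contrasts between 2 groups. The largest difference was 0.146, for actin between the genotypes at 20 d, and the mean ratio was higher in null for each control at both ages. The lowest exact permutation p of the 12 tests were 0.0238 and 0.0397, both for GAPDH, with age in wild type and between the genotypes at 3 d (adjusted p = 0.238 for each). Single differences could not pass adjustment with 5 arrays a group, so the check does not exclude differences in RNA quality. No 2 arrays held identical values.

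The alternatives were quantile normalization and median centring of the arrays, no filter and a stricter filter, pseudocounts of 1 and 64, eBayes without trend and robust settings, array weights, the replicate number as a block, only the groups of the contrast in the fit, and leaving out each array in turn. For the ageing score they were 50 and 200 probe sets a side. Added after the data were seen were fits without the null arrays numbered 5, which lay farthest from their groups, scores without the probe sets of the tissue lists, and a score from the respiratory chain and neuron lists.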

Results

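Gene expression was measured in dissected brains of Drosophila melanogaster with Affymetrix Drosophila 2 arrays, one colour, 1 sample per array. Wild-type flies and flies null for miR-34 were sampled at 3 d and at 20 d of natural ageing, with 5 arrays in each of the 4 groups and 20 in all. The titles give a single label for each genotype, so loss of miR-34 cannot be told apart from other differences between the lines. miR-34 is a microRNA, a short RNA that lowers the output of messenger RNAs it pairs with. Each array held 18952 probe sets. The median signal of an array was 20.1 ± 1.00 units in 3 d wild type (mean ± SD, n = 5), 24.2 ± 0.677 in 20 d wild type, 21.3 ± 0.402 in 3 d null and 22.3 ± 0.754 in 20 d null. Arrays of the same group correlated at Pearson's r from 0.989 to 0.997 across the 9806 probe sets tested, and no pair of arrays from different groups exceeded 0.971. The first principal component held 45.0% of the variance and separated the ages, and the second held 32.3% and separated the genotypes. The labels do not say whether the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value below.

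**Figure D1:**
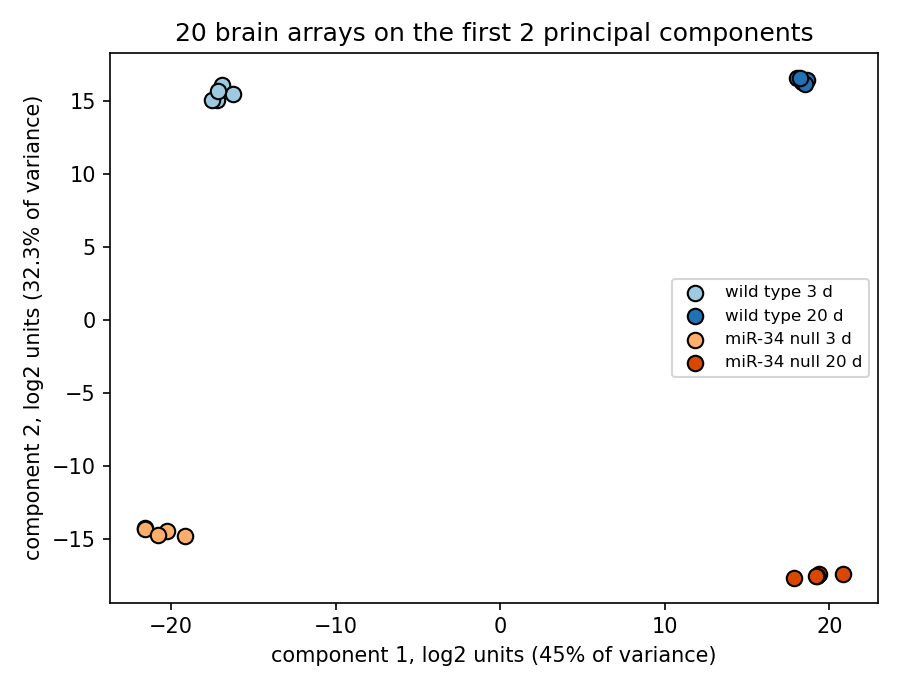
Scores of the 20 arrays on principal components 1 and 2 of the log2(signal + 16) values of 9806 probe sets, in log2 units; each point is an array, coloured by genotype and age. The 4 groups of 5 arrays form 4 separate clusters, with age along component 1 (45.0% of the variance) and genotype along component 2 (32.3%).

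The first comparison asked how young brains differ between the null and wild-type lines. In 3 d null brains, muscle genes, serine proteases of the digestive tract and some immune genes such as DptB were higher than in 3 d wild type, and many photoreceptor and glutathione enzyme genes and the odorant-binding protein genes Obp83b and Obp69a were lower. The digestive protease Jon99Fi had a signal of 533 ± 65.7 in 3 d null (n = 5) and 1.06 ± 0.573 in 3 d wild type, a log2 fold change of 5.00 ± 0.066 (SE). The receptor gene mthl8 rose from 0.13 ± 0.139 to 432 ± 21, by 4.79 ± 0.052 on the log2(signal + 16) scale, a scale that understates changes of low genes. CG6912 went the other way, from 1000 ± 42.5 in wild type to 45.3 ± 6.70 in null, a change of -4.06 ± 0.059 (adjusted p = 1.58e-24 by limma). In all, 1513 probe sets were higher and 1806 lower in null, of which 134 and 87 differed at least 2-fold. A chance division of these arrays is unlikely, with 3319 calls against at most 462 in other splits. Splits of arrays do not test chance between animals, here or in the comparisons below.

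The other genes with the 10 largest rises were CG16826 (4.70), whe (4.28), the digestive protease Jon25Biii (4.12), CG15814 (3.65), CG8562 (3.18), the trypsin alphaTry (3.18), CG13947 (3.15) and CG18180 (3.11), given as log2 fold changes. The other large falls were those of Meics (-3.42), CG9377 (-3.19), the chemosensory receptor gene Ir76a (-3.02), CG43085 (-2.66), the odorant-binding protein genes Obp83b (-2.62) and Obp69a (-2.46), the cuticle protein gene Cpr49Ag (-2.56), the eye pigment gene se (-2.44) and pkm (-2.30). All had adjusted p at or below 4.1e-19 by limma, and the naming rule took only genes in which the 5 arrays of each group did not overlap. Such a separation held for 24.3% of all probe sets tested, where chance alone gives 0.79%.

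Muscle genes rose together at 3 d: 17 of 20 measured members were higher in null and none was lower (18 and none adjusted over the list alone), with a median log2 fold change of 0.63 (camera adjusted p = 1.13e-13). Mlp60A, a muscle LIM protein gene, rose by 1.38 ± 0.053, Prm, which encodes paramyosin, by 1.36 ± 0.057, and the troponin C gene TpnC41C by 1.34 ± 0.058. A list of digestive enzymes assembled after the values were seen had 17 of 20 members higher, 18 adjusted over the list alone, with a median of 2.40. Many of these members passed the expression filter only through the 3 d null arrays, so the count describes the pattern and does not test it. Its mean log2 signal was 7.39 ± 0.034 in 3 d null against 5.32 ± 0.019 in 3 d wild type, 5.45 ± 0.0045 in 20 d wild type and 5.58 ± 0.019 in 20 d null. Both lists mark tissues other than brain, and the digestive list includes the proteases named above, so it adds no separate test of them.

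Some immune genes were higher in 3 d null, and the calls of all 3 immune lists were lost with an estimated correlation. Of 6 measured antimicrobial peptide genes 4 rose and 2 fell (camera adjusted p = 0.0239, and adjusted p = 0.162 with an estimated correlation). DptB, a diptericin, rose by 1.79 ± 0.15, Mtk, metchnikowin, by 1.26 ± 0.054 and Drs, drosomycin, by 1.04 ± 0.052. Of 12 bomanin, Turandot and other immune-induced genes 6 rose and 3 fell (adjusted p = 0.016, and adjusted p = 0.118 with an estimated correlation), led by the stress gene TotC at 1.42 ± 0.043 and by BomBc3 at 1.39 ± 0.059. Of 21 peptidoglycan recognition and Toll and Imd pathway genes 7 rose and 2 fell, with PGRP-SC2 at 2.28 ± 0.064 and PGRP-SB1 at 1.27 ± 0.059 (adjusted p = 0.0455, and adjusted p = 0.358 with an estimated correlation). The median of that last list was 0.03, and -0.02 after median centring of the arrays, and its call was also lost with quantile normalization.

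Photoreceptor and phototransduction genes fell in 3 d null: 16 of 23 were lower and 1 was higher (16 lower and 2 higher adjusted over the list alone), with a median of -0.28 (camera adjusted p = 5.96e-09, and adjusted p = 0.00593 with an estimated correlation). The photoreceptor surface gene chp fell by 1.57 on the log2 scale, the channel gene trpl by 1.55 and the scaffold gene inaD by 1.23. Glutathione and antioxidant genes fell in 14 of 27 members and rose in 1 (adjusted p = 0.00153, and adjusted p = 0.00879 with an estimated correlation), among them GstD9 (-0.73), GstD10 (-0.51) and GstE1 (-0.51), which encode glutathione transferases. Odour- and taste-related genes of the head fell in 6 of 12 and rose in 2 (adjusted p = 0.000445, and adjusted p = 0.0158 with an estimated correlation), with Obp28a at -1.32 ± 0.08 beside Obp83b and Obp69a. That list names genes of the head rather than of the brain. Its changes, here and below, were not tested apart from tissue content. Eye pigment genes fell in 6 of 13, with se, st (-1.01) and Rab32 (-0.75), at adjusted p = 0.0325, and adjusted p = 0.0692 with an estimated correlation. In the sex composition list 4 of 7 genes were lower, with Obp99b at -2.17 ± 0.045 and the yolk protein gene Yp3 at -0.61 ± 0.09, at adjusted p = 0.0196, and adjusted p = 0.0542 with an estimated correlation. Both genes are also in the fat body list, so this list does not tell sex composition apart from fat body. It also mixes markers of both sexes, so a shift in a single direction does not test sex composition in any comparison. Except where given, counts adjusted over the list alone equalled those over all probe sets.

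The median centring of arrays turned the 3 d split into 1083 higher and 2595 lower, since it moved the median change of all probe sets from -0.01 to -0.06. The muscle list and the genes named above kept their direction under quantile normalization and median centring.

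The second comparison asked the same of 20 d brains. In 20 d null brains, photoreceptor genes and genes of the fat body list such as Cyp4g1 and Yp3 were lower than in 20 d wild type. TotC, the cell-stress genes Hsp27 and Gadd45 and the dopamine transporter gene DAT were higher. The call of the fat body list was lost, at adjusted p = 0.0505 with an estimated correlation. That list marks tissue other than brain, and its change was not tested apart from tissue content. TotC reached 1260 ± 25.3 units in 20 d null against 191 ± 4.19 in 20 d wild type (n = 5 each), a log2 fold change of 2.62 ± 0.043. CG14125 was at 42.3 ± 2.62 in null and 1430 ± 50.7 in wild type, a change of -4.63 ± 0.048, and Cyp4g1, a cytochrome P450 of hydrocarbon synthesis in oenocytes, was at 96.7 ± 13.9 and 1600 ± 57.7, a change of -3.85 ± 0.082. By limma, 2051 probe sets were higher and 2410 lower in null, 70 and 167 of them by at least 2-fold. A chance division of these arrays is unlikely, with 4461 calls against at most 999 in other splits.

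The other 9 highest genes were mthl8 (4.94), CG3088 (3.81), CG15814 (3.59), CG12009 (2.55), CG14419 (2.43), CG8620 (2.33), CG8343 (2.26), CG7299 (2.14) and the odorant-binding protein gene Obp56g (2.13). The other 8 lowest were CG6912 (-4.07), CG5506 (-3.69), CG15531 (-3.54), Meics (-3.37), CG7910 (-3.32), CG43085 (-3.32), CG16904 (-3.31) and the chitin deacetylase gene Cda9 (-3.30). All of them had adjusted p at or below 6.36e-17. The naming rule took only genes whose 2 groups did not overlap, which held for 33.1% of all probe sets tested.

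Photoreceptor genes were lower in 17 of 23 members and higher in 1 (19 lower and 1 higher adjusted over the list alone), with a median of -0.50 (camera adjusted p = 5.97e-08, and adjusted p = 0.0084 with an estimated correlation). chp fell by 1.81, inaD by 1.61 and trpl by 1.60 on the log2 scale. Fat body genes were lower in 11 of 16 and higher in 2 (adjusted p = 0.000676, and adjusted p = 0.0505 with an estimated correlation), with Cyp4g1, Obp99b (-1.86) and Yp3 (-1.40). Gnmt, which the list named but which was not matched, went the other way, with 1270 ± 62.4 units in 20 d null and 716 ± 39.5 in 20 d wild type. Obp99b, Yp3 and fit (-1.04), a gene of the fat body around the head, also led the sex composition list, of which 4 of 7 were lower (adjusted p = 0.0178, and adjusted p = 0.0505 with an estimated correlation). A list of chitinases, chitin deacetylases and mucins assembled after the values were seen was lower in 7 of 12 members, with a median of -0.46. Its camera adjusted p of 8.4e-06, and 0.012 with an estimated correlation, describes values already seen and is no separate test. The list was assembled to mark the proventriculus and peritrophic matrix, not brain, and its changes here and below were not tested apart from tissue content.

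Genes of neurons were higher in 16 of 45 and lower in 2, with a median of 0.08 (adjusted p = 0.023, and adjusted p = 0.344 with an estimated correlation), a call also lost with quantile normalization. The dopamine transporter gene DAT rose by 0.60 ± 0.065, Tbh, which makes octopamine, by 0.43 ± 0.13 and the GABA receptor gene Rdl by 0.42 ± 0.055. Lists that did not pass the test still held called members. BomBc3 (1.53) and Listericin (1.44) were higher among immune-induced genes, of which 6 of 12 rose and 4 fell (adjusted p = 0.0567). pirk, an inhibitor of the Imd pathway, rose by 1.04 ± 0.057 in the recognition and pathway list, where 8 of 21 rose and 4 fell (8 and 5 adjusted over the list alone, list adjusted p = 0.192). The small heat shock gene Hsp27 rose by 1.00 ± 0.061 (list adjusted p = 0.115). Gadd45 (0.93), the cell death gene grim (0.89) and the caspase gene Dronc (0.73) rose in a list of cell death and stress genes where 10 of 18 were higher and 4 lower (adjusted p = 0.12). The insulin receptor gene InR (-0.76) and the insulin-like peptide gene Ilp5 (-0.52) fell in a list with 8 of 19 higher and 5 lower (adjusted p = 0.439). Adjusted over the list alone, 9 of these 19 were higher and 5 lower, and the other counts of this paragraph were the same except where given.

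The balance of higher and lower calls at 20 d depended on scaling. Median centring gave 3066 higher and 1509 lower, with the median change of all probe sets at 0.06.

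The effects of genotype at the 2 ages resembled each other across probe sets: 989 probe sets were higher in null at both ages and 1219 lower at both, against 316.5 and 443.9 for independent lists, and 224 were called in opposite directions. The log2 fold changes correlated at r = 0.484 across probe sets, which are not independent replicates, and these comparisons share no arrays. Genes with at least a 2-fold difference at both ages in the same direction came to 92 probe sets, 28 higher and 64 lower, and 66 single genes. Of these 66 genes, 75.8% lay on the chromosome that carries mir-34, by the gene order of the assembly Release 6 plus ISO1 MT, against 43.9% of all genes tested.

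The gene next to mir-34 in that order was Fmr1, which encodes the fragile X protein. Its stronger probe set was higher in null by 0.28 ± 0.053 at 3 d (adjusted p = 0.00022) and by 0.36 ± 0.053 at 20 d (adjusted p = 6.56e-06). Its other probe set, at 24.5 ± 3.21 units in 3 d wild type, changed by -0.11 ± 0.087 and 0.01 ± 0.087 and was not called. CAH7, at 0.07 ± 0.045 and -0.02 ± 0.045, and gammaSnap2, at -0.08 ± 0.047 and -0.11 ± 0.047, were not called at either age. The other 7 neighbours with a probe set, Npc2c, CG33631, CG33784, nerfin-2, Alp13, ATPsynepsilonL and knk, lay below the expression filter. mir-34 itself, the published miR-34 target Eip74EF and the eye colour gene w were not analysed here, as no probe set was listed for them, so the null genotype was not checked from the arrays.

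The third comparison asked how wild-type brains change between 3 d and 20 d. Many immune, detoxification and fat body genes rose with age, and nearly all genes of the mitochondrial respiratory chain fell, as did most genes of neurons. The fat body and haemocyte lists mark tissues other than brain, and the changes with age were not tested apart from tissue content. The list calls of the respiratory chain, of immune recognition and of haemocytes were lost, at adjusted p = 0.212, 0.111 and 0.11 with an estimated correlation. DptB rose from 18.2 ± 6 to 378 ± 65.6 units (n = 5 each), a log2 fold change of 3.53 ± 0.15, and Cyp4g1 from 67.6 ± 9.06 to 1600 ± 57.7, a change of 4.28 ± 0.082. Nplp3, a neuropeptide-like precursor gene, fell from 609 ± 28.9 to 58.7 ± 3.74, a change of -3.06 ± 0.05, and the corneal protein gene retinin from 426 ± 28.8 to 37.4 ± 2.55, a change of -3.05 ± 0.048. By limma, 3013 probe sets rose and 2436 fell, and 341 of the rises but 30 of the falls were at least 2-fold. A chance division of these arrays is unlikely, with 5449 calls against at most 1674 in other splits.

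The other genes with the largest rises were CG15531 (3.58), CG7910 (3.48), CG16904 (3.23), Sgp (3.12), the chitinase gene Cht4 (2.76), Lst, which encodes the hormone limostatin (2.73), CG4408 (2.72) and Mtk (2.59). The other large falls were CG7203 (-3.48), CG7214 (-2.78), CG4000 (-2.71), Obp83b (-1.92), the cuticle protein gene Cpr62Bb (-1.78), the digestive protease Jon65Aiii (-1.68), CG10725 (-1.65) and CG13360 (-1.58). All had adjusted p at or below 5.58e-14.

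All 6 measured antimicrobial peptide genes rose, CecB by 1.08 ± 0.069 beside DptB and Mtk (camera adjusted p = 0.000445, and adjusted p = 0.0447 with an estimated correlation). Among immune-induced genes 11 of 12 rose and 1 fell (adjusted p = 3.09e-06), including the prophenoloxidase gene PPO1 at 2.11 ± 0.083, Listericin at 1.79 ± 0.075 and the thioester protein gene Tep4 at 1.49 ± 0.048. Of 21 recognition and pathway genes 15 rose and 3 fell, with PGRP-SB1 at 2.47 ± 0.059 and GNBP3 at 1.51 ± 0.042 (adjusted p = 4e-04, and adjusted p = 0.111 with an estimated correlation). Haemocyte markers rose in 10 of 15 and fell in 3 (11 and 3 adjusted over the list alone), with the scavenger receptor gene Sr-CI at 1.60 ± 0.063 and NimC1 at 1.43 ± 0.045 (adjusted p = 0.0216, and adjusted p = 0.11 with an estimated correlation).

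Cytochrome P450 and other detoxification genes rose in 34 of 40 and fell in 1 (35 and 1 adjusted over the list alone), with a median of 0.58 (adjusted p = 1.66e-11, and adjusted p = 0.00027 with an estimated correlation). Cyp6g1 rose by 2.30 ± 0.038, Cyp309a1 by 2.11 ± 0.079 and Cyp309a2 by 2.04 ± 0.058. Fat body genes rose in 15 of 16, and in 16 adjusted over the list alone, with a median of 0.86 (adjusted p = 2.41e-09), led by Cyp4g1, fit (2.02) and the glucosidase gene tobi (1.83). The sex composition list, which also holds fit, rose in 4 of 7 and fell in 0 (camera adjusted p = 0.0709). It was called with quantile normalization and with no filter. Genes of insulin, adipokinetic hormone and nutrient signalling rose in 14 of 19 and none fell, with Akh at 1.10 ± 0.052 and the lipase gene Lip4 at 1.09 ± 0.051 (adjusted p = 0.000345). Genes that break down branched-chain amino acids and fatty acids rose in 19 of 24 and fell in 2, with Tmlh at 1.06 ± 0.088 and the aminotransferase gene Bcat at 0.87 ± 0.097 (adjusted p = 6.58e-05, and adjusted p = 0.0493 with an estimated correlation).

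Of 56 genes of the respiratory chain and ATP synthase, 55 fell and 1 rose, with a median of -0.30 (camera adjusted p = 1.4e-14). These genes also moved together between arrays of a group, and the list gave adjusted p = 0.212 with an estimated correlation. ND-18 of complex I fell by 0.58, ND-B18 by 0.49 and ATPsyndelta by 0.41 on the log2 scale. Genes of neurons fell in 34 of 45 and none rose, with a median of -0.28 (adjusted p = 8.86e-09, and adjusted p = 0.0268 with an estimated correlation). Among them ple, which encodes tyrosine hydroxylase, changed by -0.65 ± 0.19, the vesicular GABA transporter gene VGAT by -0.57 ± 0.051 and the serotonin transporter gene SerT by -0.56 ± 0.063. Quantile normalization turned the split of all calls into 2234 higher and 3182 lower and median centring into 1541 and 4787. Centring moved the median change of all probe sets to -0.14, and with it the list medians were -0.46 for the respiratory chain, -0.44 for neurons and 0.42 for detoxification genes. With quantile normalization they were -0.17, -0.22 and 0.54.

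The fourth comparison asked how null brains change over the same span. Many immune, detoxification and fat body genes rose and most respiratory chain and neuron genes fell in null as well, and digestive and muscle genes fell from their high level at 3 d. These changes too were not tested apart from tissue content. The list calls of antimicrobial peptides, of immune recognition and of the respiratory chain were lost, at adjusted p = 0.196, 0.169 and 0.262 with an estimated correlation. Gnmt, glycine N-methyltransferase, rose from 171 ± 4.24 to 1270 ± 62.4 units (n = 5 each), a log2 fold change of 2.78 ± 0.039, and Arc2, a relative of the synaptic gene Arc, from 92.7 ± 4.55 to 652 ± 43.8, a change of 2.62 ± 0.047. Listericin rose from 16.8 ± 3.02 to 201 ± 20.3, a change of 2.73 ± 0.075. Jon99Fi went from 533 ± 65.7 to 1.17 ± 0.972, a change of -4.99 ± 0.066. By limma, 3142 probe sets rose and 2550 fell, 294 and 128 by at least 2-fold. Quantile normalization turned this split into 2600 higher and 3000 lower, and median centring into 2634 and 2935. A chance division of these arrays is unlikely, with 5692 calls against at most 2542 in other splits.

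The other large rises were CG3088 (4.02), CG8620 (2.76), CG9377 (2.69), CG14419 (2.43), Ance-3 (2.36), CG8343 (2.31) and CG4408 (2.23), and the other large falls CG14125 (-4.76), CG3819 (-4.32), the digestive proteases and trypsin Jon25Biii (-4.01), Jon65Aiii (-3.76), yip7 (-3.55) and alphaTry (-3.43), CG8562 (-3.17), CG5399 (-3.11) and CG11458 (-3.09). All had adjusted p at or below 8.43e-19. The digestive enzyme list fell in 15 of 20 members and rose in 5, with a median of -2.22. Muscle genes fell in 12 of 20 and rose in 4 (adjusted p = 0.0144, and adjusted p = 0.0413 with an estimated correlation), with TpnC41C at -2.33 ± 0.058, TpnC4 at -1.50 ± 0.075 and the flight muscle actin gene Act88F at -1.31 ± 0.06.

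All 12 immune-induced genes rose (adjusted p = 1.01e-07), with Tep4 at 1.73 ± 0.048. Of 6 antimicrobial peptide genes 5 rose and 1 fell, DptB by 1.78 ± 0.15 and Mtk by 1.73 ± 0.054 against Drs at -1.19 ± 0.052 (adjusted p = 0.0395, and adjusted p = 0.196 with an estimated correlation). Recognition and pathway genes rose in 14 of 21 and fell in 2, with pirk at 1.62 ± 0.057 (adjusted p = 0.00262, and adjusted p = 0.169 with an estimated correlation), and haemocyte markers rose in 10 of 15 and fell in 3, with Sr-CI at 1.71 ± 0.063 (adjusted p = 0.0164, and adjusted p = 0.094 with an estimated correlation). Detoxification genes rose in 31 of 40 and none fell (adjusted p = 2.41e-09), with Cyp6g1 at 1.72 ± 0.038 and Cyp309a1 at 1.60 ± 0.079. Fat body genes rose in 11 of 16 and fell in 1 (adjusted p = 3.82e-05), with Obp99b (1.35), fit (1.32) and the lipid droplet gene Lsd-1 (1.06). This count leaves out Gnmt (2.78), a listed name that was not matched.

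The respiratory chain fell in 53 of 56 genes and rose in 2, with a median of -0.29, and -0.16 with quantile normalization (adjusted p = 2.98e-12, and adjusted p = 0.262 with an estimated correlation). ND-18 fell by 0.55 and ND-B16.6 by 0.42, while UQCR-11 of complex III rose by 0.42 ± 0.05. Genes of neurons fell in 33 of 45 and none rose (adjusted p = 5.36e-07, and adjusted p = 0.0493 with an estimated correlation), with Rop at -0.64 ± 0.044, VGAT at -0.58 ± 0.051 and the potassium channel gene Shab at -0.57 ± 0.13. Nutrient signalling genes rose in 14 of 19 and fell in 1, with Lip4 (1.01) and the lipase gene bmm (0.84), at adjusted p = 0.000937. Genes of branched-chain amino acid and fatty acid breakdown rose in 21 of 24 and fell in 2, with Tmlh (1.48) and Bcat (1.24), at adjusted p = 9.97e-05, and adjusted p = 0.0505 with an estimated correlation. Cell death and stress genes rose in 11 of 18 and fell in 4 (12 and 4 adjusted over the list alone), with Gadd45 at 1.57 ± 0.06, Irbp at 1.22 ± 0.065 and Traf4 at 0.91 ± 0.084, at adjusted p = 0.0465, and adjusted p = 0.344 with an estimated correlation, a call also lost with quantile normalization. Odour- and taste-related genes of the head rose in 10 of 12, Obp19d by 1.09 ± 0.033, at adjusted p = 0.00596, and adjusted p = 0.0493 with an estimated correlation, a call lost with no filter.

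**Figure D2:**
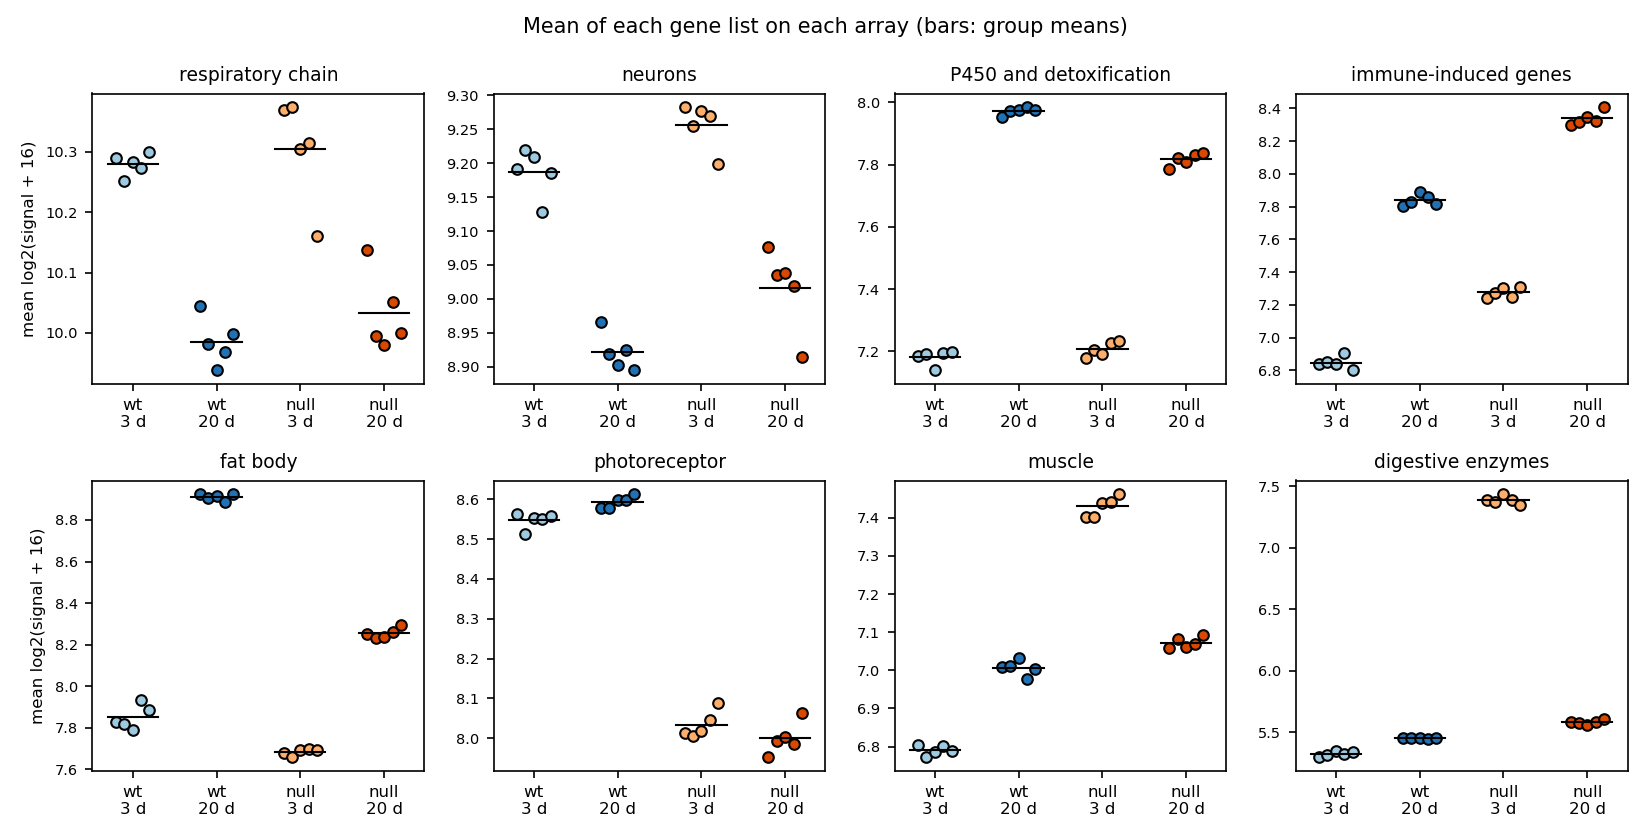
Mean log2(signal + 16) of 8 gene lists on each of the 20 arrays, each panel with its own vertical scale; points are arrays, bars are group means of 5 arrays. Respiratory chain and neuron genes are lower at 20 d in both genotypes, photoreceptor genes are lower in null at both ages, and digestive enzyme genes are at 7.39 in 3 d null against 5.32 to 5.58 elsewhere.

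The fifth comparison asked whether ageing differs between the genotypes. With age, the respiratory chain had medians of -0.30 in wild type and -0.29 in null, calls lost at adjusted p = 0.212 and 0.262 with an estimated correlation, and neurons had -0.28 and -0.26. With quantile normalization these medians were -0.17 and -0.16 for the respiratory chain and -0.22 and -0.18 for neurons. After median centring they differed more, at -0.46 and -0.33 for the respiratory chain and -0.44 and -0.29 for neurons. Many muscle and odour-related genes changed with age by different amounts. So did some fat body, antimicrobial and detoxification genes, lists whose calls were lost, at adjusted p = 0.0793, 0.145 and 0.0505 with an estimated correlation. A negative interaction means a smaller rise or larger fall with age in null. Cyp4g1 had an interaction of -3.46 ± 0.12 on the log2 scale, since it rose by 4.28 in wild type and by less in null, where its signal was 47.7 ± 7.27 at 3 d and 96.7 ± 13.9 at 20 d (n = 5 each). CG14125, with an interaction of -5.37 ± 0.067, rose in wild type from 930 ± 44.5 to 1430 ± 50.7 and fell in null from 1570 ± 120 to 42.3 ± 2.62. CG3088 had 4.39 ± 0.079, with 258 units in 20 d null and at most 9.25 ± 0.905 in the other groups. By limma, 746 probe sets had a positive and 920 a negative interaction, 33 and 169 of them at least 2-fold. Other splits, which mixed the genotypes within each age, made at most 1 call against 1666. Mixing puts the genotype effect into the spread, so these splits do not test the interaction by itself.

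The other largest positive interactions were CG8343 (2.90), CG9377 (2.53), Obp83b (2.32) and CG14419 (2.25), and the other largest negative ones Jon99Fi (-5.22), CG5506 (-5.15), CG5399 (-5) and CG11672 (-4.69), all at adjusted p at or below 7.81e-15. Muscle genes had negative interactions in 16 of 20 and a positive one in 1 (17 and 2 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 2.33e-11), among them TpnC41C (-1.52), the troponin T gene up (-1.33) and Mp20 (-1.05). Odour- and taste-related genes had positive interactions in 7 of 12 and negative ones in 2 (8 and 3 adjusted over the list alone), with a median of 0.67 (adjusted p = 7.81e-05, and adjusted p = 0.0084 with an estimated correlation), among them the pheromone-binding protein gene lush (1.28) and Obp28a (1.12). Fat body genes had negative interactions in 7 of 16 and positive ones in 3 (8 and 3 adjusted over the list alone), with tobi (-1.27) and the fatty acid synthase gene FASN2 (-0.93) beside Cyp4g1, at adjusted p = 0.00288, and adjusted p = 0.0793 with an estimated correlation. Gnmt, listed there but not matched and so not counted, had a positive interaction of 1.76. The fat body median was -0.18, and -0.06 after median centring. Antimicrobial peptide genes had negative interactions in 3 of 6 and a positive one in 1, with DptB (-1.74), Drs (-1.47) and Mtk (-0.87), at adjusted p = 0.0192, and adjusted p = 0.145 with an estimated correlation. Detoxification genes had negative interactions in 15 of 40 and positive ones in 2 (15 and 3 adjusted over the list alone), with Cyp4e1 (-1.76) and Cyp309a2 (-1.34) against Ugt35A1 (1.21), at adjusted p = 0.0057, and adjusted p = 0.0505 with an estimated correlation. The median of that list was -0.03, and 0.09 after median centring, which moved the median interaction of all probe sets to 0.13. The digestive enzyme list, which marks tissue other than brain, had a median interaction of -2.23, beside that of the muscle list. None of these list interactions, that of the odour- and taste-related genes included, was tested apart from tissue content.

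For the respiratory chain the interaction was called for UQCR-11 alone, at 0.56 ± 0.071 (list adjusted p = 0.563), and for neurons for nAChRalpha3 alone, at 0.17 ± 0.056 with adjusted p = 0.0444, a call that 13 of the 20 fits without 1 array did not make, at adjusted p from 0.0537 to 0.0853 (list adjusted p = 0.474; the count adjusted over the list alone was 0). Neither p shows that the changes are equal. Single genes in lists that did not pass the test had interactions too, such as TotC (1.20), Hsp27 (0.99), Hsp26 (0.79), Gadd45 (1.00) and the tumour necrosis factor gene egr (-0.61). Median centring gave 2623 positive and 556 negative interactions in place of 746 and 920.

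**Figure D3:**
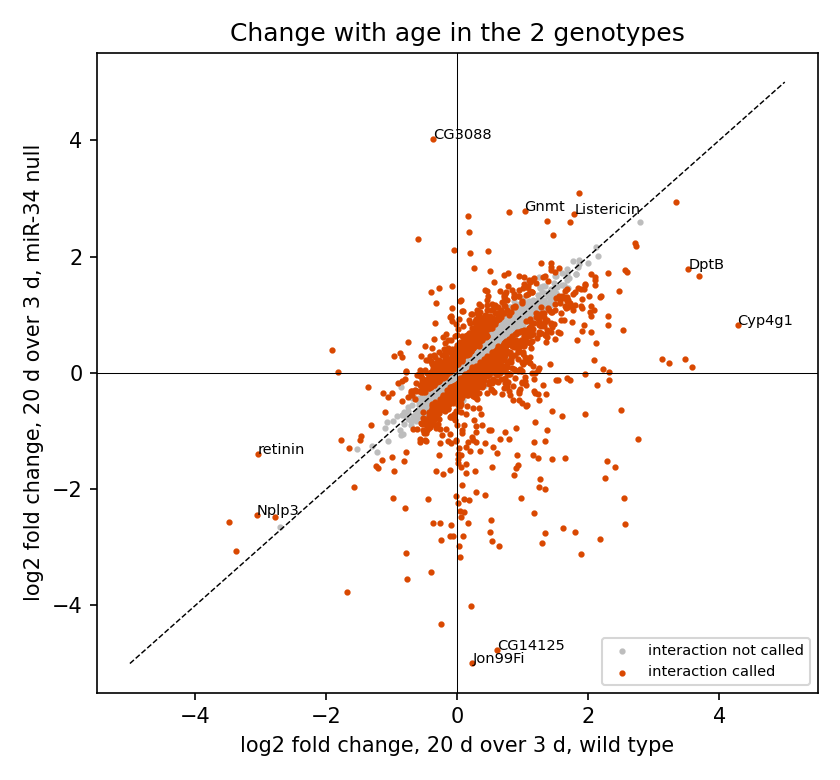
Log2 fold change from 3 d to 20 d in miR-34 null (vertical) against that in wild type (horizontal) for 9806 probe sets, on the log2(signal + 16) scale; the dashed line marks equal change, and orange points are the 1666 probe sets whose interaction passed adjusted p 0.05. The probe sets form a cloud that slopes upward (r = 0.593, slope 0.648), while Cyp4g1 rises mainly in wild type, CG3088 rises in null, and Jon99Fi and CG14125 fall in null.

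Across probe sets, the changes with age in the 2 genotypes correlated at Pearson's r = 0.593 and Spearman's rho = 0.748, and these comparisons share no array. Of the probe sets called in both, 2257 rose in both, 1746 fell in both and 218 went in opposite directions, where independent lists would share 965.4 rises and 633.5 falls.

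An ageing score placed null brains along the wild-type change with age, from the 100 probe sets that rose and the 100 that fell most clearly in wild type. The arrays that set the score and those compared were kept apart, with 3 wild-type against 5 null arrays in each of 10 choices. At 3 d, null brains scored higher than wild type by 0.442 on average, 15.1% of the wild-type difference between 3 d and 20 d, which was 2.93. At 20 d they scored differently in the other direction, at -0.734, or -25.4% of a span of 2.89. Every one of the 10 choices at each age gave p = 0.0179 in a two-sided exact permutation test, the smallest that 3 against 5 arrays allow. The probe sets were chosen as the extremes of the wild-type change. A line that differs in ways unrelated to age can therefore score nearer the middle, above wild type at 3 d and below it at 20 d. Keeping arrays apart does not remove this, so the scores do not show faster or slower ageing. A score made only from the respiratory chain and neuron lists, chosen after seeing the data, reversed the difference at 3 d to -0.0452, or -16.1% of its own span (exact permutation p = 0.151). At 20 d it gave -0.0683, or -24.3% of its own span (exact permutation p = 0.0238). The genotype effect at 3 d correlated with the wild-type change with age at r = 0.162 across probe sets, with a covariance of 0.0238. These comparisons share the 3 d wild-type arrays: unchanged groups simulated against the same controls gave r = 0.502 and a covariance of 0.00236, and with the controls split between the comparisons r was 0.120 to 0.157 and the mean covariance 0.0217.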

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

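The tests on other probe sets of the same gene, on the chromosome of all genes called, on gut tissue and on eye tissue were chosen after the result was seen, while those on the chromosome of the 66 genes, on neighbouring genes, on scaling and on other splits of the arrays were set out earlier.

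Genes at least 2-fold apart between the genotypes in the same direction at both ages came to 66, of which 75.8% lay on the chromosome that carries mir-34, where random gene sets gave a median of 43.9% and a 95% point of 54.5%, and 28.8% had another such gene within 10 genes, where random sets gave 15.2% and 25.8%, though genes that changed at least 2-fold with age in wild type also passed their 95% point for neighbours (64.7% against 61.9%). The chromosome excess was not confined to these genes: of all genes called between the genotypes 50.8% lay there at 3 d (Fisher's exact test, adjusted p = 2.24e-18), 60.5% of those that changed by at least 0.5 log2, and 48.2% at 20 d (adjusted p = 1.91e-12), against 43.9% of all genes tested and 43.9% of those called with age in wild type. The chromosome shares are in line with a different background on that chromosome in the null line, which may account for part of the genotype differences. A sequence difference under single probe sets might account for others. In the 8 genes with further probe sets, these changed 0.102 times as much in the median (95% interval 0.0363 to 0.702), too wide to decide. The ratio is taken to each gene's most changed probe set, which makes it low by construction. For the 9 genes with further probe sets that changed at least 2-fold with age in wild type it was 0.479 (0.232 to 0.933). At 3 d 1 of 3 probe sets of CTCF followed only weakly (-3.35, -2.71 and -0.24 ± 0.053), and those of smp-30 went opposite ways (-1.33 and 0.29). Both of mthl8 rose (4.79 and 3.37) and both of rtp fell (-1.42 and -1.4). An effect of miR-34 on these genes was not separated from such a background by the 2 genotypes used.

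Digestive enzyme genes were high in 3 d null brains. Gut tissue in the 3 d null samples may account for the pattern and stays open: of the 24 probe sets with a group mean over 16, 75% had their highest group mean there, but many reached 16 only in that group, so the share decides nothing. Gut tissue in only some of the 3 d null arrays was not excluded by the list, though 5 of 5 lay above all 3 d wild-type arrays in its mean. Members low in the other groups passed the filter only if high in all 5, so the mean could not decide this. Jon65Aiii and alphaTry, also above the array medians in 3 d wild type (86 ± 4.03 and 32.9 ± 3.36), had 619 ± 18.6 and 427 ± 19.3 units in 3 d null. The muscle list, another tissue marker, also rose at 3 d (median 0.63). Expression of these genes in the brain of young null flies was not tested apart from tissue content.

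Photoreceptor genes were lower in null at both ages. Scaling of the arrays was excluded, since the median change of the list was -0.28 at 3 d and -0.43 at 20 d with quantile normalization. Less eye tissue in the null samples might account for the pattern: 78.3% of the 23 measured genes were lower at both ages, between the 60% set against it and the 80% set for it. The changes of these genes correlated at r = 0.968 between the ages. Eye pigment genes were lower in 6 of 13 at 3 d and 4 of 13 at 20 d and higher in 0, with medians of -0.10 and -0.02 (camera adjusted p = 0.0325 and 0.179). The corneal gene retinin was lower in null at 3 d (163 ± 5.37 against 426 ± 28.8 units) and higher at 20 d (51.9 ± 2.64 against 37.4 ± 2.55). A direct effect of genotype on photoreceptors was not tested apart from tissue content.

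Among 100 splits of the arrays of each comparison, the real one included, 1 called at least as many probe sets as the real one, which is the real one itself, for each of the 5 comparisons. The highest other counts were 462, 999, 1674, 2542 and 1, in the order of the report, against 3319, 4461, 5449, 5692 and 1666. For the interaction the splits mixed the genotypes within each age, so their count does not test it apart from the genotype effect. With 100 splits no share below 1 in 100 was possible, and the splits do not test chance between animals.

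In 35 of 537 groups of 5 arrays, 1 array lay far from the other 4, by a gap over 0.71 of the whole range. Chance gives about 1 in 20 groups, or 26.8. Of the 35 groups, 27 were of genes and 8 of lists. The side of the array and the gap over the range are given for each. In 3 d wild type these were mthl8 (high, 0.859), CG16826 (high, 0.743), Jon25Biii (low, 0.836), CG8562 (high, 0.905), DptB (high, 0.818), Mtk (high, 0.802), Yp3 (high, 0.712), Nplp3 (low, 0.851), CG11672 (low, 0.747), lush (low, 0.731), the detoxification list (low, 0.774), the photoreceptor list (low, 0.733), the haemocyte list (high, 0.728) and the cuticle list (high, 0.735). In 20 d wild type these were CG6912 (high, 0.815), TotC (high, 0.755), CG8343 (high, 0.781), CG7299 (high, 0.754), Dronc (low, 0.875), Sr-CI (high, 0.733), the recognition and pathway list (high, 0.763), the eye pigment list (low, 0.777) and the chitin and mucin list (low, 0.869). In 3 d null these were Jon25Biii (low, 0.754), CG15814 (low, 0.859), Drs (high, 0.92), CAH2 (low, 0.767), VGAT (low, 0.73), CG3819 (high, 0.815), Shab (low, 0.72), tim (low, 0.784) and the glia list (high, 0.809). In 20 d null these were Jon25Biii (high, 0.717), Mtk (low, 0.713) and CG7910 (high, 0.747).

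Of 146 genes named, 100 changed with age by different amounts in the 2 genotypes by the interaction test, 46 with a positive and 54 with a negative value on the log2 scale. The genes were chosen for large changes, and over all probe sets tested the interaction was called for 1666 of 9806, or 17%. Positive values were those of CG3088 (4.39), CG8343 (2.90), CG9377 (2.53), Obp83b (2.32), CG14419 (2.25), CG7299 (2.15), CG8620 (1.97), Obp56g (1.87), Gnmt (1.76), retinin (1.65), lush (1.28), Arc2 (1.26), Ugt35A1 (1.21), TotC (1.20), Obp28a (1.12) and Gadd45 (1.00). Further positive values were those of Hsp27 (0.99), Ir76a (0.98), Listericin (0.94), CG7203 (0.91), Ance-3 (0.89), Obp69a (0.81), Hsp26 (0.79), grim (0.71), pkm (0.71), Hr38 (0.66), Cpr62Bb (0.62), Nplp3 (0.62), Hsp68 (0.61), UQCR-11 (0.56), Obp19d (0.55) and Irbp (0.54). Further positive values were those of Traf4 (0.49), pirk (0.45), ImpL1 (0.43), Tmlh (0.42), Cpr49Ag (0.39), bmm (0.37), CG10725 (0.35), Dronc (0.34), GstE1 (0.33), GstD9 (0.32), Obp99b (0.31), CG7214 (0.29), Tep4 (0.24) and nAChRalpha3 (0.17). Negative values were those of chp (-0.24), Gp93 (-0.26), CG12009 (-0.33), TpnC4 (-0.34), CG13360 (-0.38), Akh (-0.42), Ilp5 (-0.47), CG4408 (-0.49), Cyp309a1 (-0.50), tim (-0.51), Lst (-0.54), Cyp6g1 (-0.58), PPO1 (-0.60), egr (-0.61), Mlp60A (-0.62), CG43085 (-0.65), fit (-0.69) and Prm (-0.78). Further negative values were those of Yp3 (-0.79), Mtk (-0.87), FASN2 (-0.93), Mp20 (-1.05), PGRP-SB1 (-1.07), tobi (-1.27), up (-1.33), Cyp309a2 (-1.34), Drs (-1.47), TpnC41C (-1.52), DptB (-1.74), Cyp4e1 (-1.76), PGRP-SC2 (-1.85), Jon65Aiii (-2.08), CG11458 (-2.31), CG13947 (-2.52), yip7 (-2.79) and Sgp (-2.88). Further negative values were those of whe (-2.93), CG18180 (-3), alphaTry (-3.03), CG16904 (-3.06), Cda9 (-3.14), CG8562 (-3.21), CG7910 (-3.24), Cyp4g1 (-3.46), CG15531 (-3.48), Cht4 (-3.89), CG16826 (-4.07), CG3819 (-4.08), Jon25Biii (-4.22), CG11672 (-4.69), CG5399 (-5), CG5506 (-5.15), Jon99Fi (-5.22) and CG14125 (-5.37).

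Lists that differed between the genotypes in their change with age had median interactions of -0.48 (antimicrobial peptides), -0.03 (detoxification), -0.18 (fat body), -0.55 (muscle), 0.67 (odour- and taste-related genes of the head), -2.23 (digestive enzymes) and -0.60 (chitin and mucin), the last 2 assembled after the values were seen. The calls of the first 3 were lost, at adjusted p = 0.145, 0.0505 and 0.0793 with an estimated correlation, and after median centring the medians were 0.09 for detoxification and -0.06 for fat body. The ageing score of null against wild type was 0.442 at 3 d and -0.734 at 20 d, and the difference between the ages was not tested.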

How the results depend on the processing

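The fits without the null arrays numbered 5, the ageing scores without tissue lists and the score from the respiratory chain and neuron lists were chosen after seeing the data. Median centring moved counts by more than 1.5 times: 1509 lower in null at 20 d, 1541 higher and 4787 lower with age in wild type, and 2623 positive and 556 negative interactions. It moves the median of all probe sets, and the cause was not tested further. The stricter filter, which tests fewer probe sets, left 587 negative interactions. No other setting moved a count of calls by as much, from 568 to 3704 over the settings other than median centring, and leaving out single arrays gave 1410 to 1481 higher and 1604 to 1809 lower in null at 3 d and 643 to 827 positive interactions. The ageing scores kept their direction and p under 0.05 (exact permutation) with 50 or 200 probe sets a side, quantile normalization, no filter, without the tissue lists and without any null array, from 0.368 to 0.606 at 3 d and from -0.959 to -0.531 at 20 d. With the respiratory chain and neuron lists alone, the 3 d score was reversed at -0.0452 and the cause was not tested. The correlation of ageing effects between genotypes was 0.573 with quantile normalization and 0.572 with no filter, and that of the genotype effect at 3 d with wild-type ageing was 0.168 with no filter, where the cause was not tested. Of 4885 values of named genes under alternatives, 4868 kept their direction and side of the threshold, none was reversed and 17 missed the threshold, all of them for nAChRalpha3 in the interaction and RpL15 with age in wild type. Of 41 list calls, 21 held with an estimated correlation, 38 with quantile normalization and 40 with no filter, which called 6 and 13 further lists. With age in wild type, the median of the recognition and pathway list went from 0.35 to 0.23 with quantile normalization and 0.19 with median centring, that of nutrient signalling from 0.30 to 0.15 and that of amino acid and fatty acid breakdown from 0.45 to 0.29 with median centring. That of neurons at 20 d went from 0.08 to 0.15 with median centring. The alternative with 8-base miR-34 sites was not run, as no site search was made. fry, which asks only whether a list moves one way on balance, called 95 of 130.

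Whether the repeat numbers mark shared handling was left open. In deviations from group means, same-numbered pairs had a median r of 0.11 and other pairs of -0.0316. Of 30 same-numbered pairs 16 correlated above 0.1, but the lowest was at -0.184, so the numbers were not taken as a pairing, and 7 of 20 arrays correlated best with an array of their own number. On component 4, with 2.88% of the variance, arrays numbered 1 scored 3.33, 4.69, 6.09 and 9.11 in the 4 groups, and the null arrays numbered 5 scored -9.92 and -11.2. With the number as a replicate block the counts higher and lower were 1593 and 1870 at 3 d, 2125 and 2494 at 20 d, 3079 and 2550 with age in wild type, 3224 and 2675 in null, and 765 and 951 for the interaction. The block gave ageing scores of 0.531 and -0.827 and kept 39 of 41 list calls. It did not call the recognition and pathway list at 3 d or the cell death list with age in null, and it also called the cell death list in the interaction. Signals near 16 units or below are compressed by the pseudocount, so that fold changes against such groups are understated.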

Other observations

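All tests in this part were of lists fixed earlier, except those of the chitin and mucin list and the cuticle list, chosen after seeing the data.

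Proteasome subunit genes rose with age in null in 13 of 26 members, 11 adjusted over the list alone, and none fell, and the list did not pass the test with the values as deposited (camera adjusted p = 0.102) but did with quantile normalization and with no filter. Prosalpha3 rose by 0.24 ± 0.033. Hsp68 rose with age by 1.02 ± 0.1 in wild type and by 1.64 ± 0.1 in null, in a list of heat shock genes with adjusted p = 0.757 and 0.824. The clock gene tim fell with age in null by 0.79 (list adjusted p = 0.588). Gat, the GABA transporter gene of glia, changed by -0.88 ± 0.056 with age in wild type, where 11 of 23 glia genes fell and 6 rose (adjusted p = 0.131). GstE9 rose with age in wild type by 1.68 ± 0.044 (list adjusted p = 0.386). Of 29 cytosolic ribosomal protein genes, 5 fell with age in wild type and 1 rose, and none of either adjusted over the list alone (adjusted p = 0.102), with RpL15 at -0.22 ± 0.078 (adjusted p = 0.0195). The call of RpL15 was lost without the 20 d wild-type array numbered 2 (0.0536) or 3 (0.0558) and with quantile normalization (0.0822). The ribosomal list turned direction with scaling, with a median of -0.07 as deposited and 0.07 with quantile normalization, and passed the test with quantile normalization and with no filter. Gp93 rose with age in wild type by 0.44 ± 0.048 in the protein folding list (adjusted p = 0.655).

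Su(z)12, which encodes a subunit of Polycomb repressive complex 2, was higher in null by 0.49 ± 0.035 at 3 d and 0.61 ± 0.035 at 20 d, and the Polycomb list did not pass the test (adjusted p = 0.832 and 0.632). The ecdysone response list did not pass either (adjusted p = 0.569 and 0.615), and in it ImpL1 (-1.49) and Blimp-1 (-0.92) were lower at 3 d and Hr38 (1.22) was higher at 20 d. CAH2 was lower at 3 d by 1.19 in the glia list (adjusted p = 0.604). The piRNA pathway gene aub was at -0.88 ± 0.057 at 3 d in the list of RNA interference and transposon control (adjusted p = 0.545). Cyp28d2 (1.74) and Ugt35C1 (-1.53) went opposite ways at 3 d, where 11 of 40 detoxification genes were higher and 11 lower (12 and 12 adjusted over the list alone, adjusted p = 0.716). Ire1 was at -0.47 ± 0.053 at 20 d (protein folding list adjusted p = 0.8). The chitin and mucin list had a positive mean of 0.45 and a median of 0.08 at 3 d (adjusted p = 0.00502, and adjusted p = 0.0741 with an estimated correlation) and rose with age in wild type in 8 of 12 and fell in 3 (adjusted p = 0.0169, and adjusted p = 0.111 with an estimated correlation). It fell with age in null in 8 of 12 and rose in 2 (adjusted p = 0.000126, and adjusted p = 0.0258 with an estimated correlation). It had negative interactions in 7 (adjusted p = 6.38e-11, and adjusted p = 0.000652 with an estimated correlation). These p describe values already seen. Cuticle genes were lower in 7 of 13 and higher in 3 at 3 d (adjusted p = 0.0391, and adjusted p = 0.0741 with an estimated correlation).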
